A study of Mus musculus with 6 samples.

How the data were processed

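Total RNA from frozen liver of 3 wild-type and 3 Itpr2 knockout mice was labelled with Cy3 and hybridised to Agilent arrays, per the labels' protocols. Each array has 44397 spots, of which 1377 are controls. The deposited scanner tables hold intensity values made by Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 10.7.3.1 per the submitters' processing notes, and both are given since the sources differ. The processed intensity in the deposited tables is background-subtracted by that software, per the file headers, and is not scaled between arrays. The authors also deposited a matrix of log2 values for 20644 probes. Set against the scanner values, that matrix matched log2 signals scaled to the 75th percentile and centred on each probe's median, with higher values for more signal. Its column medians were 0.00207, -0.0094, 0.00497, -0.0127, 0.0106 and 0.00617 for WT 1, WT 2, WT 3, KO 1, KO 2 and KO 3. The rule by which its probes were chosen is not given in the sources used here. Its columns for KO 2 and KO 3 correlated best, across probes, with the scanner values of KO 3 and KO 2, at 0.9997 and 0.9996, and the 4 other columns with their own array. Both are knockout arrays, so the genotype comparison is not touched, and the scanner tables decide which array is named here.

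Values were log2 of the processed intensity minus each array's 75th percentile. Control spots and 818 spots that the software marked as outliers were left out and spots of the same probe were averaged. Of 39429 probes, 28324 were given 1 gene symbol through accessions in a gene table of assembly GRCm38.p6, 0 had several and 11105 had none. That table served only for names and for which genes neighbour each other, and no coordinates are given, since the assembly of the array design is not given in the sources used here. A probe entered the fit if it was well above background on all 3 arrays of at least 1 genotype, which left 22302 probes. The probe with the highest mean stood for its gene, which left 17996 genes, 13666 of them with a symbol. Where a gene was not well above background on any array of a genotype, the fold is a bound, taken between means of log2 values with, on each array of the dim genotype, the higher of the dim probe's own signal and the lowest signal well above background.

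Genotypes were compared with limma (lmFit and eBayes, two-sided, version 3.58.1 in R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 44 in all, were tested with camera at an inter-gene correlation of 0.01 where at least 5 members were measured, on the 17880 genes without a missing value, with adjustment over the 42 lists tested. Camera with an estimated correlation and fry were alternatives. Single values were compared by exact permutation over the splits of the arrays, which cannot give a two-sided p under 0.1. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule takes the inositol trisphosphate receptors, up to 15 genes per direction past the threshold with no overlap of the genotypes, filled to 10 by smallest unadjusted p, and from each called list its members past the threshold, or else the 3 members with the smallest p, and from lists not called up to 3 members with the highest level. Neighbours of Itpr2 outside that rule, muscle and fat genes, and Chac1 and Asns were chosen after their values were seen. Of the genes the rule takes, 3 are not reported here.

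Slides 1 and 2 each held both genotypes, and the scans followed the slides. WT 1, WT 2 and KO 1 were on slide 1 and WT 3, KO 2 and KO 3 on slide 2. The slide was therefore fitted as a block and values were also taken within each slide. Values within slide 1 rest on KO 1 as the only knockout array, and those within slide 2 on WT 3 as the only wild-type array. Other alternatives were normexp background correction, quantile and median scaling, the authors' matrix, other filters and probe rules, other variance priors, array weights, the replicate number as a block, each array left out, and outlier spots kept. Normexp was planned on the mean signal, and the median signal was used because the tables read here held no mean signal column. The procedure was tested on simulated data with the spread of these 17880 genes and changes placed in 50 genes of each size. For this comparison 2% of genes with a log2 change of 0.5 were recovered at the adjusted threshold, 14% at 1, 76% at 2 and 100% at 3, so smaller changes would mostly be missed. Changes of all sizes were placed in the same simulated data, and many true changes loosen the adjusted threshold. With few changed genes the recovery can be lower than these shares, large changes included.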

Results

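Liver RNA of 6 mice aged 23 months was profiled on 1-colour Agilent arrays, with 3 mice that lack Itpr2 (a receptor that releases calcium from the endoplasmic reticulum) and 3 wild-type mice. Per the series design the mice were independent animals, and the labels give no treatment. Between 57.5% and 59.5% of the probes were well above background on each array, no spot was saturated, and the number of arrays limits the precision of every value. Levels are log2 signals relative to the 75th percentile of the same array, and changes are knockout minus wild type.

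The comparison asks how the liver transcriptome of old mice differs without Itpr2. The targeted gene itself had a level of 3.07 ± 0.018 (SD, n = 3) in wild type and 2.37 ± 0.17 (SD, n = 3) in the knockout, a log2 change of -0.69 ± 0.13 (SE). All 3 knockout arrays, at 2.54, 2.38 and 2.20, lay below the wild-type arrays for Itpr2, and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. The limma adjusted p of Itpr2 was 0.810, so it did not pass the threshold of 0.05. Within each slide, the Itpr2 change was -0.52 on slide 1 and -0.79 on slide 2. The related receptors Itpr1 and Itpr3 had log2 changes of -0.0086 ± 0.24 (SE) and -0.094 ± 0.22 (SE). A single probe stands for Itpr2, and its place relative to the deleted part is not given in the sources used here, so this level does not by itself check the labels.

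Mansc4, which encodes a protein with a MANSC domain and lies beside Mrps35 on chromosome 6, was the 1 gene of 17996 that passed the adjusted threshold, and it fell in the knockout. It was well above background on all 3 wild-type arrays and on 0 of 3 knockout arrays, so its level was at least 3.45-fold lower. The limma adjusted p of 0.00699 belongs to the signals as measured, near background in the knockout, and does not test this bound. Within slide 1 the Mansc4 level was at least 3.41-fold lower and within slide 2 at least 4.05-fold. The call was lost, with 0 genes past the threshold, when WT 1, WT 2 or any of the 3 knockout arrays was left out, with the replicate block (adjusted p = 0.0750), without the 2 muscle arrays (0.313) and under both normexp corrections. The fitted log2 change of Mansc4 turned to 1.07 with the planned normexp correction, which 2 arrays distort, and was -0.17 with the trimmed one. The probe is dropped when all 6 arrays must be above background. A single probe stands for Mansc4, whose match to the DNA of the knockout was not tested.

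Other genes in the same stretch of chromosome 6 differed in both directions. Of the 34 measured genes in a fixed list of Itpr2 neighbours, 3 fell and 2 rose when adjusted over the list alone, and 0 passed over all genes, where limma gave 9 of them an unadjusted p under 0.05. The genes that fell were Tm7sf3, with a log2 change of -0.75 ± 0.14 (SE), Med21, a subunit of the Mediator complex, with -0.67 ± 0.13, and Mrps35, a protein of the mitochondrial ribosome, with -0.63 ± 0.14. The genes that rose were Ppfibp1, with a log2 change of 0.74 ± 0.15 (SE), and Kcnj8, a potassium channel subunit, with 0.83 ± 0.21. Ints13, the next measured gene after Itpr2, had a log2 change of 0.54 ± 0.15 (SE) and Arntl2, well above background on 2 of 3 knockout arrays, one of -1.70 ± 0.58, and neither passed. Smco2 was not well above background in wild type and was at least 1.56-fold higher. As a set these neighbours changed in either direction by the mixed test of fry (adjusted p = 0.000299). Their median change was 0.042 while camera, which compares a set with other genes, ranked them lower (adjusted p = 0.948), and the medians within slides 1 and 2 were 0.060 and 0.023.

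**Figure D1:**
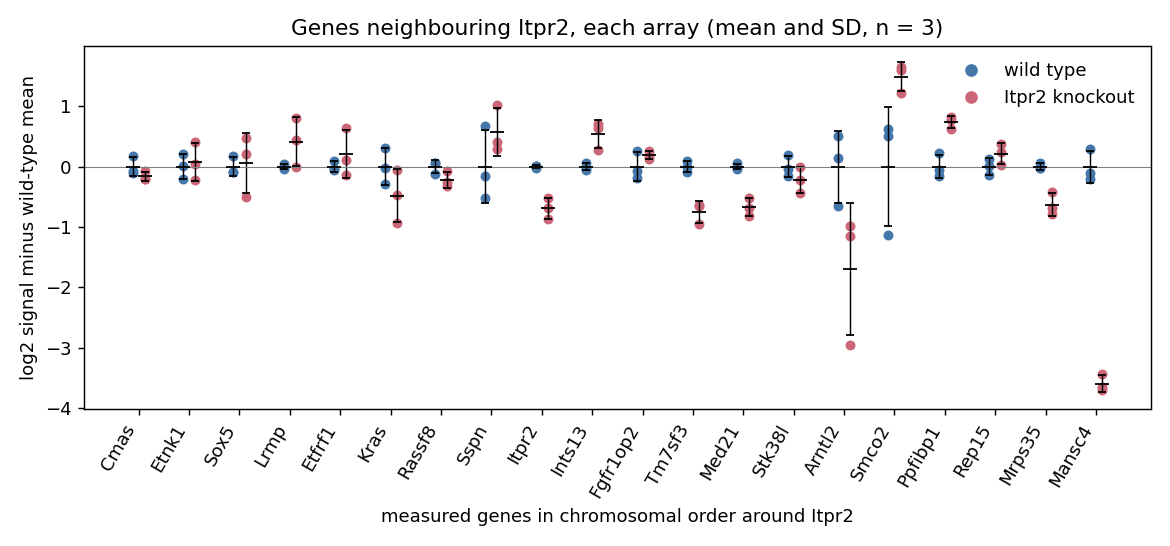
Log2 signal of measured genes around Itpr2 in chromosomal order (horizontal axis), each minus its wild-type mean (vertical axis, log2), with 1 point per array and bars for the mean and SD of 3 arrays. Tm7sf3, Med21 and Mrps35 lie lower on the knockout arrays and Ppfibp1 higher, and Mansc4 in the knockout and Smco2 in wild type were not well above background, so their plotted distances are no measured folds.

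Across the whole liver transcriptome the genotypes were not set apart. The share of the squared distance between arrays that lay between genotypes was 21.0%, and 4 of the 10 splits of the arrays gave as much (exact permutation p = 0.4). The limma fit gave 1104 genes at an unadjusted p under 0.05, of which 625 were higher and 479 lower in the knockout, where chance gives about 900. Genotypes did not overlap for 2153 genes, or 12.04%, where chance gives 10%. With arrays centred on their median the split was 274 higher and 627 lower.

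The named genes next in order after Mansc4 did not pass the threshold and are given as values, with limma adjusted p between 0.761 and 0.810. Dmbt1, a mucosal defence glycoprotein, was not well above background in wild type and was at least 4.57-fold higher in the knockout. Slc23a3, well above background on 1 of 3 wild-type arrays, had a log2 change of 1.40 ± 0.20 (SE). The long non-coding RNA Lncpint had one of 1.00 ± 0.15, the adrenergic receptor gene Adrb3 one of 1.30 ± 0.23, and Rictor, a component of the mTORC2 complex, one of 0.74 ± 0.13. Nyap1, Enpp6, Emid1, Ubxn7 and Zfp30 completed the 10 higher genes, with log2 changes from 0.62 for Zfp30 to 1.31 for Enpp6, which was well above background on 1 of 3 wild-type arrays. On the lower side Mmp7, a matrix metalloproteinase well above background on 1 of 3 knockout arrays, had a log2 change of -2.17 ± 0.37 (SE), the surfactant protein gene Sftpd one of -1.42 ± 0.20, and Pdxp one of -1.60 ± 0.30. Tmem254a and Tmem254c, near-identical copies whose probes may share signal and whose values are therefore uncertain, had changes of -1.15 and -1.37. Ppp2r2b was not well above background in the knockout and was at least 1.88-fold lower, and Dnajc2, St6galnac4 and Tor3a had log2 changes of -0.64, -0.99 and -1.09.

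Genes of fatty acid use ranked lower in the knockout. In the list of fatty acid oxidation genes driven by PPARA, the nuclear receptor of the fasting liver, 38 of 42 measured members had a lower mean and the median change was -0.46 (camera adjusted p = 5.12e-12, and adjusted p = 0.588 with an estimated correlation). None of its members passed alone by limma, and 8 had an unadjusted p under 0.05. The scores of this list overlapped between genotypes, at -0.21 on WT 1 and -0.16 on KO 2 (exact permutation p = 0.2), while KO 3 had -0.73. Over the omission of 1 array its median ran from -0.58 (without KO 2) to -0.30 (without KO 3). Acot1 and Acot2, which hydrolyse acyl-CoA, had log2 changes of -1.91 ± 0.50 (SE) and -1.38 ± 0.43, and the carnitine acetyltransferase gene Crat one of -1.17 ± 0.25. In the list of lipid droplet genes 19 of 26 members had a lower mean, with a median of -0.36 (camera adjusted p = 0.00012, and adjusted p = 0.588 with an estimated correlation). The fatty acid transporter gene Cd36 had a log2 change of -0.83 ± 0.18 (SE), G0s2, an inhibitor of lipolysis, one of -1.11 ± 0.36, and Fitm1 one of -2.17 ± 0.65. With the slide as a block the medians were -0.44 and -0.33, and within slides 1 and 2 they were -0.36 and -0.45 for fatty acid oxidation and -0.70 and -0.16 for lipid droplets. Adipoq, a fat cell gene, had levels of 0.81 on KO 3 and -1.46 on WT 1 and was well above background on 1 of the other 4 arrays.

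Interferon response genes and secreted factors of senescent cells also ranked lower. Of 49 measured interferon response genes 46 had a lower mean, with a median of -0.43 (camera adjusted p = 1.39e-12, and adjusted p = 0.588 with an estimated correlation). Oasl1, a gene of that response, had a log2 change of -0.75 ± 0.19 (SE), and the chemokine gene Cxcl10 one of -1.34 ± 0.41. The interferon median was -0.17 within slide 1, -1.04 within slide 2 and -0.70 with the slide as a block. WT 3 stood apart with an interferon score of 0.62 where the other wild-type arrays had -0.30 and -0.24. It was the only wild-type array on slide 2, and without it the interferon median was -0.16. Among secreted factors of senescent cells 24 of 35 members had a lower mean, with a median of -0.32 (camera adjusted p = 0.000117, and adjusted p = 0.588 with an estimated correlation), and the chemokine genes Ccl3 and Ccl7 had changes of -1.55 ± 0.39 (SE) and -1.21 ± 0.40. This median was -0.35 within slide 1, -0.34 within slide 2 and -0.24 with the slide as a block. Senescence arrest genes had a median of -0.055, with 12 of 21 members lower, and did not pass (camera adjusted p = 0.235). Gadd45g, a growth arrest gene among them, had a log2 change of 1.64 ± 0.38 (SE) and did not pass either (limma adjusted p = 0.810).

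Markers of Kupffer cells, of monocytes and macrophages and of T and NK cells ranked lower. All 17 measured genes of the Kupffer cell list had a lower mean, with a median of -0.52 (camera adjusted p = 3.73e-07, and adjusted p = 0.588 with an estimated correlation). Cdh5 among them, with a log2 change of -0.18, is also in the list of endothelial cell markers. Kupffer cell scores overlapped between genotypes, at -0.42 on WT 2 and -0.32 on KO 1 (exact permutation p = 0.2). Cd5l, C1qa and Folr2 had log2 changes of -0.72 ± 0.22 (SE), -0.64 ± 0.24 and -1.01 ± 0.40. Monocyte and macrophage markers had a median of -0.48, T and NK cell markers -0.52 and MHC class II genes -0.53, with camera adjusted p of 2.01e-08, 2.53e-06 and 0.016. With an estimated correlation these lists had adjusted p of 0.588, 0.704 and 0.783. Monocyte and macrophage scores overlapped too, at -0.32 on WT 2 and -0.24 on KO 3 (exact permutation p = 0.2). Over the alternatives with the preset correlation, the monocyte and macrophage median ran from -0.65 to -0.27, the latter without KO 2. Within slide 1 the medians were -0.31 for Kupffer cells, -0.28 for monocytes and macrophages, -1.08 for T and NK cells and -0.93 for MHC class II, and within slide 2 they were -0.70, -0.69, -0.55 and -0.32. With the slide as a block they were -0.52, -0.52, -0.73 and -0.66. For T and NK cells and for MHC class II, the score of KO 3, at 0.38 and 0.33, lay above all wild-type arrays. The MHC class II call was lost without WT 2, KO 1 or KO 2 (camera adjusted p of 0.0513, 0.390 and 0.216), with medians of -0.54, -0.23 and -0.31. With the planned normexp correction the calls for MHC class II, T and NK cells and secreted factors of senescent cells were lost, with adjusted p of 0.601, 0.133 and 0.715. Endothelial and stellate cell markers had medians of 0.094 and 0.11 and did not pass, with adjusted p of 0.428 and 0.302. Neutrophil markers had scores of 2.34, -1.22 and 1.47 on KO 1, KO 2 and KO 3 and did not pass (adjusted p = 0.231). With the slide as a block they were called (camera adjusted p = 0.0412, median 1.01), though the medians within slides 1 and 2 were 2.52 and -0.48.

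Chaperone and stress genes ranked lower as well. Of 20 heat shock genes 18 had a lower mean, with a median of -0.30 (camera adjusted p = 2.63e-06, and adjusted p = 0.588 with an estimated correlation), and Stip1 and Hsph1, both cochaperones, had changes of -0.58 ± 0.16 (SE) and -1.12 ± 0.41. The heat shock median was -0.15 within slide 1, -0.35 within slide 2 and -0.25 with the slide as a block. Of 30 genes of the endoplasmic reticulum stress response 19 had a lower mean, with a median of -0.17 (camera adjusted p = 0.000483, and adjusted p = 0.588 with an estimated correlation), with Syvn1 at -0.70 ± 0.19 (SE), Ddit3 at -0.57 ± 0.15 and Atf3 at -1.04 ± 0.32. Members with large changes the other way were Chac1, measured on 2 of 3 knockout arrays, at 1.73 ± 0.66 (SE) and Asns at 2.55 ± 1.36, with levels of 1.22 on KO 1 and -4.74 on KO 2. Within slide 1 that median was 0.030, within slide 2 -0.39 and with the slide as a block -0.18, and the call was lost without KO 2 (adjusted p = 0.0859). Antioxidant genes under NRF2 and cholangiocyte markers had medians of -0.10 and -0.23, with camera adjusted p of 0.00601 and 0.016, and adjusted p of 0.588 and 0.704 with an estimated correlation, and 25 of 33 and 15 of 18 members had a lower mean. In the NRF2 list Ephx1, an epoxide hydrolase, and Aox1 had log2 changes of -0.49 ± 0.17 (SE) and -0.42 ± 0.19, while Osgin1 had one of 0.65 ± 0.25, against the ranking of its list. Mmp7 was the 1 cholangiocyte marker that fell when adjusted over the list alone. Within slides 1 and 2 the medians were -0.19 and -0.052 for antioxidant genes and -0.45 and 0.16 for cholangiocytes. With the slide as a block they were -0.14 and -0.14, and the cholangiocyte call was lost (adjusted p = 0.0805). The antioxidant call was lost without WT 2, KO 1 or KO 3 (adjusted p of 0.0847, 0.128 and 0.0961, medians of -0.11, -0.086 and -0.050), and the cholangiocyte call without WT 2 or KO 2 (adjusted p of 0.665 and 0.212, medians of -0.071 and -0.049). Array weights ended the antioxidant call (adjusted p = 0.0519) and the trimmed normexp correction the cholangiocyte call (adjusted p = 0.622).

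A smaller number of liver functions ranked higher. Of 26 cholesterol synthesis genes 23 had a higher mean, with a median of 0.30 (camera adjusted p = 8.15e-05, and adjusted p = 0.588 with an estimated correlation). Dhcr7 and Pmvk, both enzymes of the pathway, had log2 changes of 0.60 ± 0.24 (SE) and 0.51 ± 0.21. The cholesterol median was 0.57 within slide 1, -0.076 within slide 2 and 0.23 with the slide as a block. Hepatocyte markers had a median of 0.14 and acute phase genes one of 0.21, with camera adjusted p of 0.0209 and 0.0292 and adjusted p of 0.588 and 0.840 with an estimated correlation. Their medians were -0.035 and 1.02 within slide 1, 0.16 and -0.15 within slide 2, and 0.064 and 0.30 with the slide as a block, where the hepatocyte call was lost (adjusted p = 0.151). The hepatocyte call was also lost without WT 1, WT 2, KO 2 or KO 3 (adjusted p of 0.0775, 0.0807, 0.130 and 0.102, medians of 0.12, 0.12, 0.16 and 0.071), and the acute phase call without WT 2, KO 1 or KO 3 (adjusted p of 0.364, 0.471 and 0.0536, medians of 0.11, -0.024 and 0.21). Both were lost with quantile normalization (adjusted p of 0.434 for hepatocytes and 0.203 for acute phase, medians of 0.0049 and 0.052), without the background filter (0.0605 and 0.0899) and with the trimmed normexp correction (0.727 and 0.601). The hepatocyte call was lost too with the mean of a gene's probes and without the 2 muscle arrays (0.0804 and 0.248), and the acute phase call with array weights, the slide as a random block and the planned normexp correction (0.265, 0.0697 and 0.0594). With that correction the medians of hepatocyte, cholesterol synthesis and cholangiocyte lists had the other sign, with adjusted p of 7.12e-05, 0.0205 and 0.0205.

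Lists of calcium handling in the endoplasmic reticulum and of its contacts with mitochondria, the functions closest to Itpr2, had medians of -0.020 and -0.017 and did not pass (camera adjusted p = 0.289 for each). Canx, a chaperone of the endoplasmic reticulum, had a log2 change of 0.036 ± 0.13 (SE). Apart from the Itpr2 neighbours, lists without a call for which the median, the mean and camera differed in sign were bile acid genes (median 0.0059, mean -0.080, ranked lower), male-biased liver genes (median -0.082, mean 0.21, ranked higher), matrix genes of fibrosis (median 0.022, mean -0.0021, ranked lower) and immediate early genes (median -0.0079, mean 0.015, ranked lower).

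**Figure D2:**
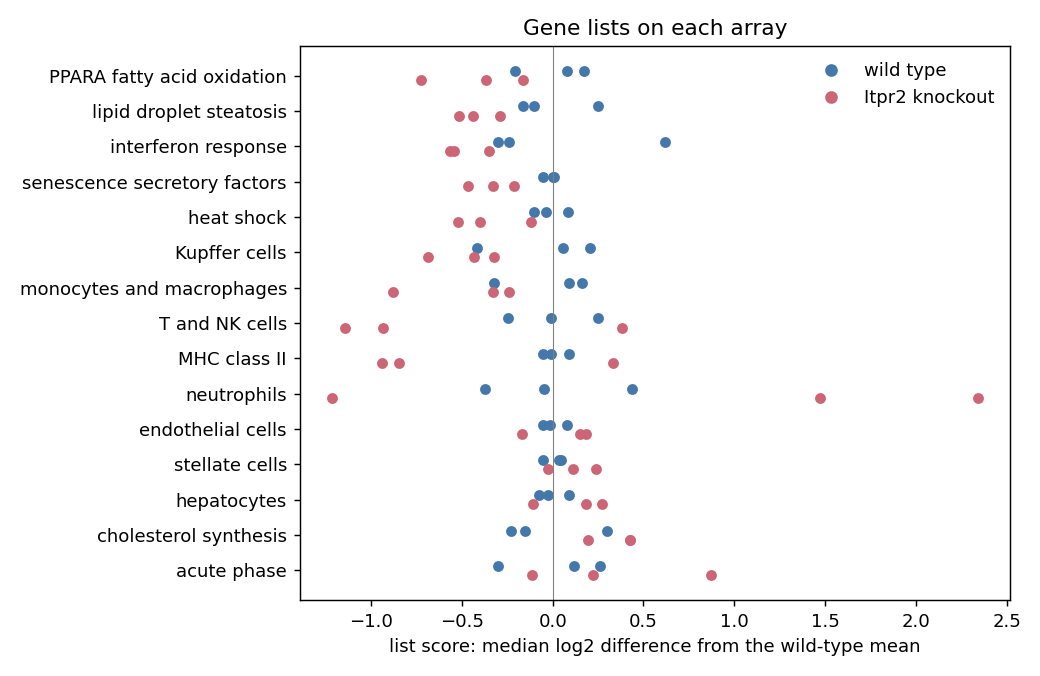
Scores of 15 gene lists (vertical axis) on each array, as the median log2 difference of the members from their wild-type means (horizontal axis), with 1 point per array and no error bars. Heat shock scores lie between -0.52 and -0.12 on the knockout arrays and between -0.10 and 0.084 on the wild-type arrays, while neutrophil scores run from -1.22 to 2.34 within the knockout. Scores of fatty acid oxidation, Kupffer cells, monocytes and macrophages, T and NK cells and MHC class II overlap between the genotypes.

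In all, camera called 15 of 42 lists with a preset correlation of 0.01, 12 lower and 3 higher, and 0 with an estimated correlation, where the smallest adjusted p was 0.588. By fry, whose directional test asks whether the genes of a list move on balance one way without comparing them with other genes, 0 lists passed, and its mixed test for change in either direction called 1, the neighbours of Itpr2. Other splits of the same arrays, which mix the genotypes, gave up to 21 called lists, so the number of calls does not set the genotypes apart.

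Skeletal muscle transcripts were present on 1 array of each genotype. All 28 muscle genes were well above background on both WT 1 and KO 3, and 20 of them on none of the other 4 arrays. Their median log2 excess over the mean of those arrays was at least 5.22 on WT 1 and at least 5.86 on KO 3, where a signal not well above background counts as the lowest signal above it. Over the 6 muscle genes measured on all arrays it was 3.54 and 3.44. Mylpf among these 6 had no such excess, at 0.257 on WT 1 and -0.015 on KO 3. Mb, the myoglobin gene, had levels of 3.80 on WT 1 and 3.83 on KO 3 and was not well above background on the other 4 arrays. Without these 2 arrays, an alternative chosen after seeing the data, the 12 lists that ranked lower were still called by camera and 0 genes passed the adjusted threshold by limma, with 1234 at an unadjusted p under 0.05.

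**Figure D3:**
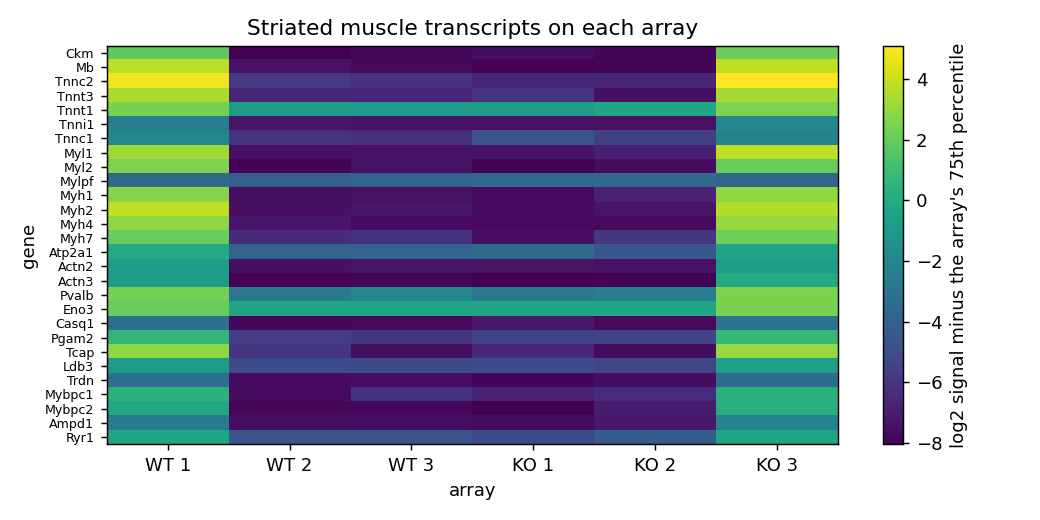
Levels of 28 muscle genes (vertical axis) on each array (horizontal axis), as colour on a scale of log2 signal minus the 75th percentile of the array. Tnnc2, a fast muscle troponin gene, has 4.81 on WT 1 and 5.08 on KO 3, and was not well above background on the other arrays.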

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

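The trimmed normexp correction and the omission of the 2 arrays with muscle transcripts were chosen only after results were seen; the other alternatives were planned. The Itpr2 level kept its direction and stayed short of the adjusted threshold in all 21 alternatives. Over the omission of 1 array, genes at unadjusted p numbered 674 (without WT 2) to 1696 (without KO 1), genes changed 0 to 1 (0 without WT 1, WT 2, KO 1, KO 2 or KO 3, each of which leaves fewer arrays), gene lists called 11 to 18, the Itpr2 level -0.78 to -0.60 and the separation of genotypes 21.7% to 29.5%. With the replicate block 0 genes passed, and 16 lists were called. Same-numbered arrays, taken as deviations from their genotype means, had correlations across genes of -0.19, 0.042 and -0.28. The highest such correlation was 0.296, between WT 1 and KO 3, the 2 muscle arrays. These values give no sign that the numbers pair the mice, but so few of them cannot exclude it. With probes above background on all 6 arrays, which leaves out Mansc4, and without the 2 muscle arrays, 0 genes passed. Gene lists called fell to 0 with an estimated correlation and 0 by fry. The slide as a block added calls for neutrophil, female-biased liver and oxidative phosphorylation genes (camera adjusted p of 0.0412, 0.00693 and 0.0248).

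Planned normexp on the median signal gave 0 genes changed, 5947 genes at unadjusted p, 25 gene lists and a separation of genotypes of 47.7%. On KO 1 and KO 2, 16 and 45 spots lay more than 100 below their local background, down to -9339 and -77185, against 0 on the other arrays, and the fitted background SD was 149.6 and 1182, against at most 3.99 elsewhere. The log2 change turned to 1.07 for Mansc4, 1.21 for Ppp2r2b, 0.96 for Mmp7, 0.081 for Dnajc2, 0.70 for St6galnac4, 0.88 for Pdxp, -0.013 for Osgin1, -0.020 for Dhcr7, -0.11 for Pmvk, -0.21 for Cps1, 0.30 for Cd53, 0.44 for Atf3, 0.55 for Crat, 0.15 for Acot2, 0.66 for Ccl3, 0.66 for Ccl7, -0.36 for Egfl7 and -0.026 for Cyp2c70. List medians turned to -0.37 for acute phase, -0.43 for autophagy, -0.25 for cholesterol synthesis, 0.95 for cholangiocytes, -0.36 for endothelial cells, -0.49 for hepatocytes, -0.49 for periportal genes, 0.44 for T and NK cells, -0.32 for gluconeogenesis, 0.67 for proliferation and 0.30 for senescence secretory factors. Without those spots the separation was 23.9%, 11 of the 12 lower lists were called and 0 the other way, but 0 genes changed, genes at unadjusted p numbered 1994, and Ppp2r2b stayed turned at 0.031; the cause of that remainder was not tested. Without KO 1 the acute phase median was -0.024 (range over omitted arrays -0.024 to 0.41) and that of oxidative phosphorylation 0.12 (range -0.099 to 0.12), and the cause was not tested. Low signal over background limits dim genes most, Mansc4 among them.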

Other observations

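The tests of the Itpr2 neighbours, of cell type shares and of tissue markers were chosen only after the results were seen, while the counts over other splits and the omission of the 2 muscle arrays were set down before their values were known.

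Fat and plasma cell transcripts varied between mice within a genotype. Ucp1, the uncoupling protein of brown fat, had levels of -1.13 on KO 3 and -2.51 on WT 1 and was well above background on 1 of the other 4 arrays. Jchain, a plasma cell gene, had a log2 change of 1.77 ± 1.37 (SE), with levels from -3.06 on WT 3 to 3.41 on KO 3. Xist, the non-coding RNA of the inactive X chromosome, was well above background on all 3 arrays of both genotypes, with means of 0.15 in wild type and 0.54 in the knockout. In 4 measured genes of a list of substrain differences the median change was -0.23, which was not tested because of their small number.

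Genes beside Itpr2 differed, some higher and some lower in the knockout. Of the 34 listed neighbours 9 had an unadjusted p under 0.05, against 5.85% of other genes with a symbol (one-sided Fisher's exact p = 0.000115), and in windows of 21 neighbouring genes 0.098% of other windows held as many as the 8 around Itpr2, all of them overlapping it. Itpr2 itself is among those 8, and without it the count was 7, where windows that share no gene with it held at most 6, which argues against a chance cluster. All 7 lay on the same side of Itpr2, from Ints13 to Mrps35, and none on the other side of that window, from Sspn to Cmas. Kcnj8, a listed neighbour with a log2 change of 0.83 ± 0.21 (SE), lies outside that window. The count by side therefore does not cover every listed neighbour that differed. The highest count of any window was 10, in windows centred on Mansc4, Mrps35 and Ppfibp1 among others. A candidate explanation is DNA around the targeted allele that came with it from other cells, changing expression or the match of single probes. An effect of the targeted locus or of losing the receptor on its neighbours was not tested and stays open, since every knockout array carries both, and neighbouring genes can share regulation, so they are not independent.

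Lists of immune and fatty acid oxidation genes ranked lower by camera. Striated muscle RNA on 2 arrays was not needed for these calls, since without those arrays 12 of the 12 lists were still called lower. More cannot be concluded, since camera at the preset correlation also called up to 21 lists in splits that mix the genotypes. Fewer non-hepatocyte cells of every type in the knockout pieces cannot be told apart from other causes, because the values rest on single arrays. Such a loss would lower endothelial and stellate markers at least as far as these lists, of which the smallest immune median was that of interferon response genes, -0.430, and fatty acid oxidation genes had -0.456. It could lower only genes that non-hepatocyte cells hold. Which cells hold the interferon and fatty acid oxidation genes was not measured, so neither list stands for a number of cells. The genotype difference was 0.051 in the endothelial score (confidence limits -0.283 and 0.385 for a threshold of 0.05 in a two-sided t-test on 3 against 3 arrays) and 0.099 in the stellate score (-0.127 and 0.325), so with all arrays both lower limits lay above the list medians. With limits and medians taken again without each array this held in 2 of 6 omissions for the immune lists and in 3 of 6 for fatty acid oxidation. The limits are of array scores and the medians of changes of single genes, and these measures can differ. For Kupffer cells the score difference was -0.429 and the list median -0.517. Without WT 3, whose interferon score of 0.619 exceeds those of the other wild-type arrays, the interferon median was -0.156 and the lower endothelial limit -0.457. The lower stellate limit alone lay above the fatty acid oxidation median in 6 of 6 omissions, and above the smallest immune median in 5 of 6. The omissions are the third criterion used, chosen like the others after values were seen: the first asked that the Kupffer score minus the endothelial score separate the genotypes, which overlapped at -0.403 on WT 2 and -0.264 on KO 3, and the second used all arrays only. Under the planned normexp correction, distorted on 2 arrays, the median of endothelial cell markers was -0.36. A change in Kupffer cells or lymphocytes alone was not tested and stays open. The 10 splits of the arrays are too few for a share under 0.05: the real split called 15 lists and the highest other 21, 7 of the 10 splits called at least 15, and the split along the slides called 16. An effect of the genotype stays open as untested.

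The splits are too few for single genes as well. The real split gave 1104 genes at an unadjusted p and the highest other 1090, with 1 of 10 splits as large, and 1 gene at the adjusted threshold against 0, again 1 of 10.

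Striated muscle in the tissue piece is a candidate source of the muscle transcripts on WT 1 and KO 3. The lower of their median excesses was at least 5.22 over 28 genes, most of which have no measured level on the other arrays, and 3.44 over the 6 of them that entered the fit. White fat as a source on both arrays stays open. Its lower excess, that of WT 1, was 0.237 over the 5 genes in the fit. Over 8 genes it was 1.06 with signals as measured and at least 0.373 with signals near background raised to the lowest one above it. The wider gene set and this bound were taken only after the earlier values had been seen, and a lower bound cannot show that an excess is absent. On KO 3 the white fat excess was larger, at least 3.07 over the 8 genes, but 0.349 over the 5 in the fit. Car3 among them lay lower on KO 3, at -0.801. Brown fat markers, with 4 measured genes, had a median excess of at least 2.185 on WT 1 and 2.873 on KO 3. Elovl3 among them lay lower on both arrays, and brown fat as a source was not tested. No biological explanation was tested, since each genotype holds 1 such array.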
